A study of Mus musculus with 2 samples.

How the data were processed

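Trimethylation of lysine 27 on histone H3 (H3K27me3) is the repressive chromatin mark laid down by Polycomb repressive complex 2. It was profiled by chromatin immunoprecipitation and sequencing in whole limb tissue of mouse embryos at day 12.5 of development. Per the labels, the 2 biological replicates were pools of limbs from 88 embryos (replicate 1) and 68 embryos (replicate 2) of strain B6NCrl, each pool holding both sexes. They form 1 group, so the comparisons below are between the replicates and between genes, gene groups and regions within the tissue.

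The authors deposited 4 peak lists on mouse assembly mm10 (GRCm38): 1 for each replicate, 1 called on both replicates together (the pooled list) and 1 of peaks they termed replicated. Per the accompanying text files, the replicated list was derived from the other 3, and all 81005 of its peaks were identical in every column to a peak of the pooled list. The rule for keeping a peak was not given in the sources used here; tested on the files, 63667 of the replicated peaks (78.6%) shared at least 50% of their length, or of the other peak's length, with a peak in each replicate list, 16882 (20.8%) did so in 1 list, and 456 in neither. Because a replicated peak has the extent of the pooled call, covered shares in this list often exceeded those in both replicate lists. The aligner, the peak caller and its settings, and the type of control used were not given in the sources used here. Each peak carried a signal value made by the authors' peak caller, which is the authors' own and was used here only to rank peaks within a list. The deposited lists also gave −log10 p and −log10 q for each peak as the authors' caller computed them; the lowest −log10 p was 2.02 in each list. The lists held no read counts, so the sequencing depth of the replicates was unknown, and a list with more peaks may only have come from a deeper library.

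Promoters were defined on the GENCODE M21 annotation of GRCm38 as the window of 1 kb on each side of the 5' end of each protein-coding gene. Of 21938 such genes on chromosomes 1 to 19, X and Y, 27 with a repeated symbol were left out and 21911 were used. A promoter was called marked when at least 25% of its window lay in peaks. The replicated list was used for the main values, and each replicate list was measured in the same way to give a mean and standard deviation (SD, n = 2). No peak ended beyond the end of its chromosome in the reference sequence. Coordinates are 1-based on mm10. A gene's 5' end is the outermost annotated one, and in 1858 genes the start shared by most transcripts lay over 1 kb away from it.

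Overlap of the replicate lists was measured as the Jaccard index of covered bases, the bases in both lists over the bases in either. It was set against 200 random placements of 1 list within its chromosomes and outside assembly gaps, in a one-sided permutation test whose smallest possible p is 0.005. The same shuffles of the replicated list gave the chance share of peak bases in promoter windows, elsewhere in genes and outside genes. Each peak was placed independently, which does not keep the clustering of peaks, so these permutation p-values can be too small. A total of 17 gene lists were tested for marked promoters against all other protein-coding genes by two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 17 lists. Of the listed symbols, 1 was not in the annotation and 26 stood in more than 1 list. CpG-rich promoters were those with a CpG observed over expected ratio of at least 0.6 and a GC content of at least 50% within 500 bp of the 5' end. The X chromosome was compared with the autosomes by two-sided Fisher's exact test of marked promoters. Domains were replicated peaks joined over gaps of up to 1 kb. Shares of genes were given exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Genes are not independent replicates, since neighbouring genes can lie in 1 domain, and p-values over genes or peaks do not measure the spread between embryos.

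The gene lists, thresholds, tests and rule for naming genes were fixed before the data were examined. By that rule the text may name any Hox gene; the 4 marked members of each list with the highest covered promoter share and the 2 members with the lowest; 8 and 8 in the limb patterning list, along with Shh, Fgf8, Tbx4, Tbx5, Pitx1, Hand2, Grem1, Prrx1, Msx1 and Sox9; the genes with a 5' end in the 20 longest domains; and the 5 genes with the largest difference between the replicate lists. Other genes are named only where this is stated. Alternatives were a −log10 q of at least 2, each replicate list alone, the pooled list, the intersection of the replicate lists, windows of 500 bp and 2.5 kb, marking by at least 1 bp or at least 50% of the window, any annotated transcript start, CpG-rich promoters only, neighbouring genes within 50 kb counted as 1 locus, members of more than 1 list left out, a CpG ratio of at least 0.75, equal numbers of peaks, and joining gaps of 0 and 5 kb. Added after the data were seen were a circular shift of the peaks, the peaks found in both replicate lists, the start shared by most transcripts, a −log10 q of at least 5, and a comparison without olfactory receptors.

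The interval code was tested on simulated data against base-by-base maps in 50 draws, with 0 mismatches. For the gene list test over the 21938 annotated genes, simulated lists of 40 genes with a true marked share of 40% were called in 93.5% of 200 draws, and lists of 20 such genes in 57.0%. A call in these simulations was a Fisher's exact p under 0.05 without adjustment over lists, so the rates are not those of the adjusted test. Random lists of 40 genes were called in 4.25% of 400 draws, and lists made of 4 runs of 10 neighbouring genes in 13.25%, so that p-values for lists of clustered genes are too small. Peaks on unplaced scaffolds were left out of the comparisons. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.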

Results

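H3K27me3 was profiled in limbs of mouse embryos at day 12.5, when digit condensations form and much of the limb is still undifferentiated mesenchyme. The data were peak lists from 2 biological replicates, pools of 88 and 68 embryos of both sexes. Replicate 1 had 144548 peaks covering 58.0 Mb (2.13% of the genome), and replicate 2 had 204999 peaks covering 80.9 Mb (2.97%). The authors' list of replicated peaks held 81005 peaks over 68.2 Mb (2.504% of the genome), with a median width of 494 bp and a longest peak of 32274 bp. The replicates' mean was 2.55% ± 0.594 of the genome (SD, n = 2), and the share was 3.90% in the pooled list and 1.37% in the intersection of the replicate lists. Read depth was unknown for both replicates.

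Promoters marked in 1 replicate were largely marked in the other, although many peaks and covered bases were not shared. Of the 21911 protein-coding promoters, 3473 were marked in both replicate lists, 166 in replicate 1 alone and 670 in replicate 2 alone. The 2 lists gave the same call for 96.2% of promoters (Cohen's kappa 0.869). Covered share correlated across genes between the lists with a Spearman's rho of 0.838, where genes are not independent replicates. The 5 genes with the largest difference were all covered more in replicate 2. The mesodermal homeobox gene Meox2 had 10.6% of its window covered in replicate 1 and 83.9% in replicate 2, and the BMP antagonist gene Grem2 had 0% and 64.5%. The potassium channel subunit genes Kcng4 (8.50% and 80.4%) and Kcnmb2 (27.6% and 96.6%) and the hemojuvelin gene Hfe2 (10.4% and 81.0%) behaved in the same way. At the level of bases, the lists shared 37.4 Mb, a Jaccard index of 0.369, against a mean of 0.0146 and a maximum of 0.0153 in 200 random placements (permutation p = 0.005, the smallest that 200 placements can give). Among replicate 1 peaks, 57.2% shared at least 1 bp with a replicate 2 peak, against a mean of 6.54% in random placements, and 36.7% of replicate 2 peaks did so in return.

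In the replicated list, 4138 of 21911 promoters were marked (18.9%, exact 95% binomial interval 18.4% to 19.4%). The share was 16.6% in replicate 1 and 18.9% in replicate 2, a mean of 17.8% ± 1.63 (SD, n = 2). Promoter windows held 9.49% of peak bases, 5.65 times the shuffled mean of 1.68%. Regions elsewhere in protein-coding genes held 44.2% (1.11 times the shuffled mean), and regions outside genes held 46.3% (0.793 times; permutation p = 0.005 for each of the 3, the smallest possible). The small excess elsewhere in genes turned to 0.963 times with promoter windows of 2.5 kb. Its p can also be too small, because the shuffles did not keep the clustering of peaks. CpG-rich promoters were marked more often than others, at 21.3% of 9723 against 17.0% of 12188 (odds ratio 1.32, Fisher's exact p = 9.64e-16). By the same exact test, this direction turned when the CpG ratio had to reach 0.75, with 16.8% of 5919 promoters marked against 19.7% of the rest (p = 8.68e-07).

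Genes that pattern the limb bud carried the mark at most of their promoters. Of 59 limb patterning genes, 45 were marked (76.3%, exact 95% interval 63.4% to 86.4%), against 18.7% of other genes (odds ratio 13.6, Fisher's exact adjusted p = 9.75e-21), and the replicates gave 75.4% ± 3.60 (SD, n = 2). Several of them had windows covered to 100% in the replicated list. Shh (chromosome 5, 28456815 to 28467256), the posterior signal of the zone of polarizing activity, was covered to 100% in both replicates, as were the Wnt ligand genes Wnt7a of the dorsal ectoderm and Wnt3, and the homeobox gene Irx3. Fgf17 had 98.7% ± 1.91 over the replicates, the homeobox gene Msx1 91.3% ± 4.95, and Fgf9 77.3% ± 7.46. Fgf8, made in the apical ectodermal ridge, had 92.2% ± 1.91, and the BMP antagonist gene Grem1 had 84.8% ± 0.636. The hindlimb genes Pitx1 and Tbx4 reached 83.0% ± 15.1 and 62.5% ± 5.02 (each SD, n = 2), and the forelimb gene Tbx5 (chromosome 5, 119832668 to 119885219) had 80.1% in replicate 1 and 100% in replicate 2. Forelimbs and hindlimbs were not separated.

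Other limb patterning genes had little or no cover by replicated peaks in their promoter windows. The homeobox gene Prrx1, a marker of early limb mesenchyme, and Fgf10, its signal to the ridge, had 0% of their windows in peaks in both replicates. Gli2, a transducer of hedgehog signalling, the receptor gene Fgfr1 and the ETS factor gene Etv5 were also at 0%, and Wnt5a was at 0% in the replicated list and 1.25% ± 1.77 over the replicates. The chondrogenic factor gene Sox9, which stood in the cartilage and bone list, had 0% in the replicated list and in both replicates. Hand2, an upstream regulator of Shh, was unmarked at 11.1% in the replicated list but differed between replicates (8.85% and 29.5%). Fgfr2 and Prrx2 had 0% at their outermost 5' ends, but 30.2% and 56.6% at the start shared by most of their transcripts. Wnt7a had 0% at that start.

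**Figure D1:**
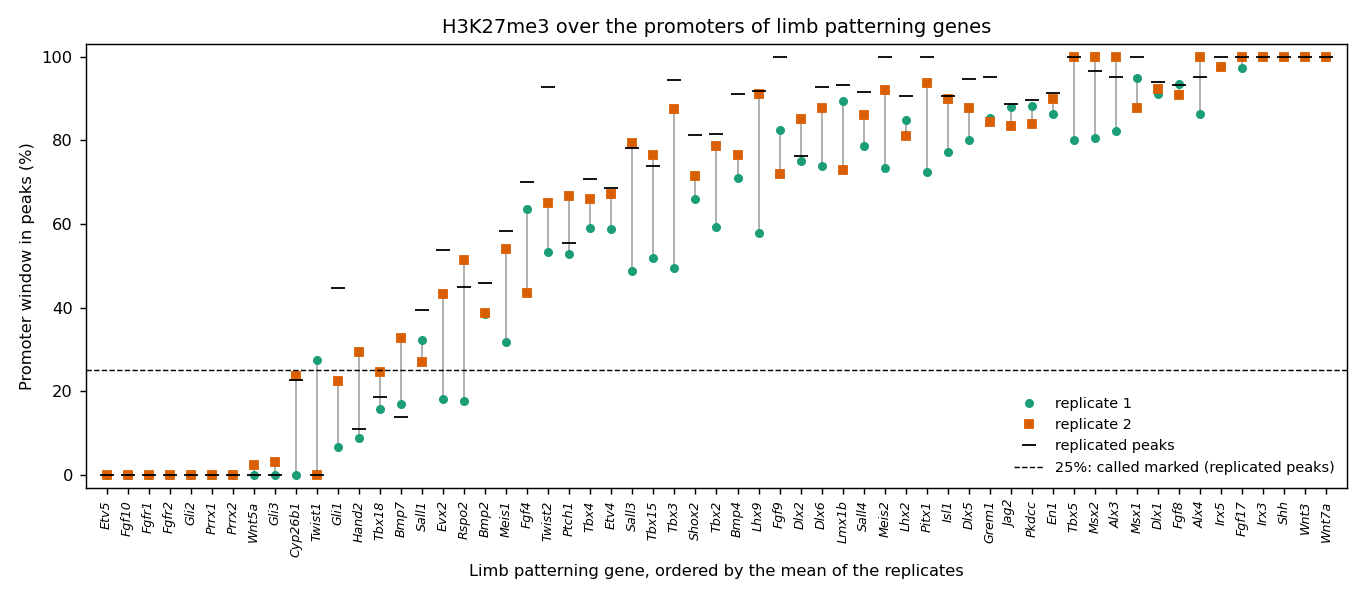
Share of the promoter window (1 kb on each side of the 5' end) in H3K27me3 peaks, in percent, for each of the 59 limb patterning genes on the x axis, ordered by the mean of the replicates. Circles are replicate 1, squares replicate 2, black dashes the replicated peaks, and the dashed line is the 25% at which a promoter is called marked; Prrx1, Fgf10, Gli2, Fgfr1 and Etv5 lie at 0% and Shh, Wnt3, Wnt7a and Irx3 at 100%.

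Lists for cell types found in the limb were marked at 43.6% to 76.3% of their promoters. In the cartilage and bone list, 21 of 39 genes were marked (53.8%; exact adjusted p = 1.84e-06), among them the cartilage signal gene Ihh and the matrix gene Matn4, both at 100% in both replicates, the matrix gene Comp (98.0% ± 2.86) and the homeobox gene Barx2 (97.5% ± 3.57; SD, n = 2). Col10a1, of hypertrophic cartilage, and the osteocalcin gene Bglap had 0%. In the skeletal muscle list, 17 of 37 genes were marked (45.9%; exact adjusted p = 0.000223). The myogenic regulators Pax7, Myod1 and Lbx1 and the skeletal actin gene Acta1 were covered to 100% in both replicates, while the contractile genes Myh8 and Myl1 had 0%. Of 39 genes of blood and endothelium, 17 were marked (43.6%; exact adjusted p = 0.000449). Gata2, Sox18 and the tight junction gene Cldn5 were at 100% in both replicates and the blood regulator Tal1 at 96.1% ± 5.58 (SD, n = 2), while Cdh5 and Csf1r had 0%. Counted as loci of neighbouring genes, muscle (44.4% against 30.8%, exact adjusted p = 0.115) and blood and endothelium (47.2%, exact adjusted p = 0.0588) no longer passed the test. In the surface ectoderm list, 29 of 38 genes were marked (76.3%; exact adjusted p = 6.14e-14). Wnt6, Wnt10a and Wnt10b were at 100% in both replicates and the claudin gene Cldn7 at 97.2% ± 3.82, while the keratin genes Krt14 and Krt10 had 0%. For neural crest, Schwann cells and melanocytes the count was 16 of 26 (61.5%; exact adjusted p = 3.01e-06). Sox10, the receptor gene Ret and the myelin gene Mbp were at 100% in both replicates and Foxd3 at 98.5% ± 2.12, while the melanocyte genes Dct and Mlana had 0%. At the start shared by most of its transcripts, Mbp had 43.4% in the replicated list.

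Nervous system transcription factors had the highest share of the 17 lists. Of 76 such genes, 74 were marked (97.4%, exact 95% interval 90.8% to 99.7%; exact adjusted p = 2.57e-50), and the count was 74 in each replicate as well. Barhl1, Neurog3, Bhlhe23 and Neurod1, which specify neuronal types, were at 100% in both replicates. The 2 unmarked members were Neurod4, with 0%, and Neurod6, with 13.6% ± 7.21 over the replicates (SD, n = 2). Among transcription factors of gut, liver, lung and pancreas, 31 of 35 were marked (88.6%; exact adjusted p = 3.30e-18), including Onecut1, the pancreatic gene Ptf1a and the thyroid gene Foxe1 at 100% in both replicates and the lung and thyroid gene Nkx2-1 at 96.7% ± 4.74. The intestinal gene Isx and the liver gene Hnf1a had 0% in the replicated list. In the kidney and gonad list the count was 26 of 30 (86.7%; exact adjusted p = 4.96e-15), with Pax2, Foxl2, Wnt9b and the nephrin gene Nphs1 at 100% in both replicates and the tubule genes Umod and Slc12a1 at 0%. In the heart list it was 16 of 25 (64.0%; exact adjusted p = 1.72e-06), with Irx4, Irx6 and Tbx1 at 100% in both replicates, Nkx2-6 at 97.0% ± 4.28, and Nppa and Bmp10 at 0%. Of 19 Wnt ligand genes, 17 were marked (89.5%; exact adjusted p = 1.18e-10), with Wnt3a, Wnt7a, Wnt7b and Wnt10b at 100% in both replicates. The 2 unmarked ones were Wnt5a and Wnt5b, and Wnt5b had 78.6% at its best covered start.

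**Figure D2:**
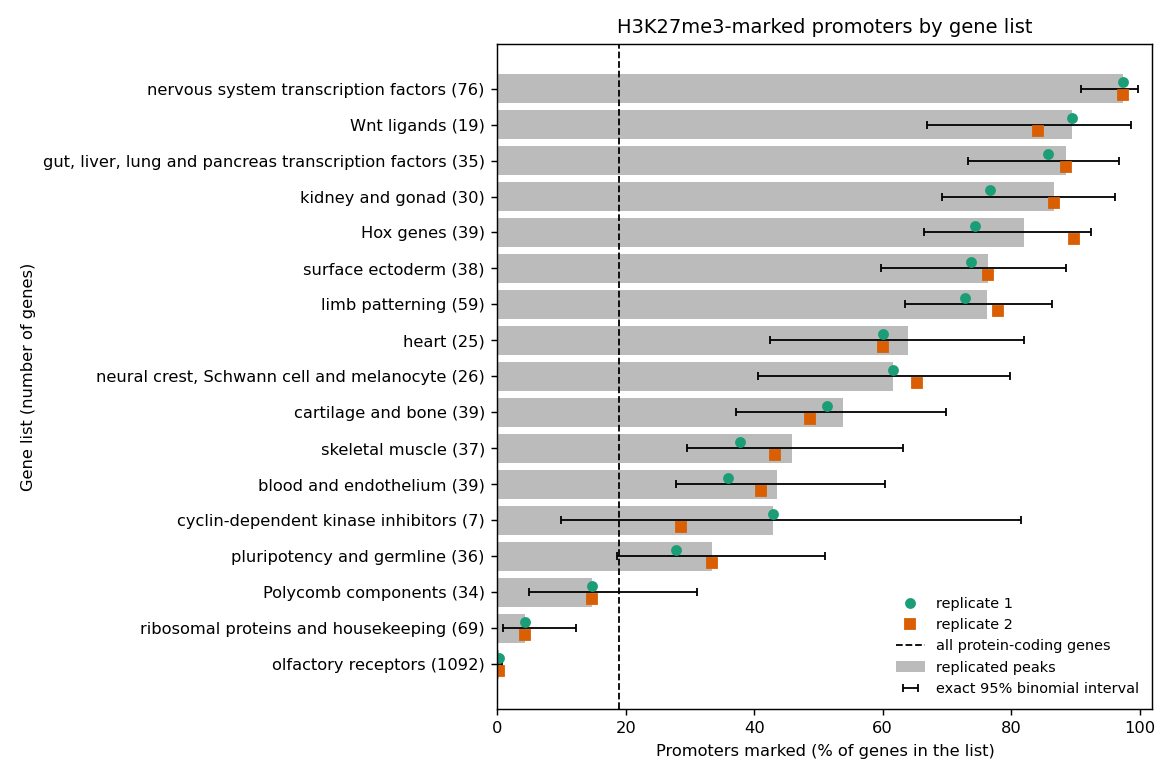
Percentage of promoters called marked in each of the 17 gene lists, with the number of genes in parentheses. Bars are the replicated peaks with exact 95% binomial intervals, circles and squares are replicates 1 and 2, and the dashed line is the share over all protein-coding genes (18.9%); the lists run from 0.183% for olfactory receptors to 97.4% for nervous system transcription factors.

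Pluripotency and germline genes were marked at 12 of 36 promoters (33.3%; exact adjusted p = 0.0377), a call that was lost in most alternatives, such as replicate 1 alone (27.8%; exact adjusted p = 0.0856) and CpG-rich promoters only (3 of 12 genes; exact adjusted p = 0.775). The marked genes included the pluripotency genes Pou5f1 (93.0% ± 9.93), Tfcp2l1 (94.2% ± 8.23), Tdgf1 (91.6% ± 11.9) and Utf1 (100% in both replicates), while the germ cell genes Asz1 and Dazl had 0% (SD, n = 2). Genes for the Polycomb complexes themselves were marked at 5 of 34 promoters (14.7%; exact adjusted p = 0.664), with Phf19 at 100% in both replicates, Pcgf5 at 96.6% ± 4.84, Epop at 91.8% ± 6.01 and the X-linked Rbbp7 at 46.6% ± 1.52, and with Cbx2 and Cbx6 at 0%. The difference from other genes was not significant and changed sign in 4 alternatives, reaching 29.4% against 23.3% when 1 bp sufficed. Of 7 cyclin-dependent kinase inhibitor genes, 3 were marked (42.9%; exact adjusted p = 0.137): Cdkn2a at 97.2% ± 3.99, Cdkn2b at 92.3% ± 1.91 and the imprinted Cdkn1c, which differed between replicates (53.2% and 19.2%). Cdkn1b and Cdkn2d had 0% in the replicated list. With any transcript start counted, 71.4% of this list was marked and the exact adjusted p was 0.00838.

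Ribosomal protein and housekeeping genes were marked less often than other genes, at 3 of 69 promoters (4.35%, exact 95% interval 0.906% to 12.2%; exact adjusted p = 0.00115), with the actin gene Actb and the ATP synthase gene Atp5b at 0%. The 3 were Rpl3, Ldha and the X-linked glycolysis gene Pgk1. At the start shared by most transcripts, Rpl3 and Ldha had 0% and the share marked was 1.45%. Olfactory receptor genes, which are silent outside sensory neurons, were marked at 2 of 1092 promoters (0.183%; exact adjusted p = 6.54e-97), namely Olfr12 and Olfr95, with 40.9% ± 21.6 and 50.6% ± 17.4 over the replicates, against 0% at members such as Olfr1 and Olfr10.

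The Hox clusters, whose genes lay down positional identity along the body and limb axes, were covered to different extents. As a list, 32 of 39 Hox promoters were marked (82.1%, exact adjusted p = 7.98e-17), with 29 in replicate 1 and 35 in replicate 2. Hox genes are neighbours within their clusters and share domains, so this p-value is too small. HoxC (chromosome 15, 102921103 to 103036852) was 89.8% ± 4.59 in peaks, HoxB (chromosome 11, 96194316 to 96368256) 77.3% ± 5.11, and HoxA (chromosome 6, 52155590 to 52260880) 37.9% ± 10.4 (SD, n = 2). HoxD (chromosome 2, 74668310 to 74765142) lay between them, with 63.2% in replicate 1 and 76.9% in replicate 2. HoxA was the least covered cluster in each replicate, and its distance from each of the others exceeded the replicate spread. No test of base cover was made between clusters. In the intersection of the replicate lists the HoxA share fell to 25.6%.

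All 10 HoxB and all 9 HoxC promoters were marked, and 16 Hox windows lay entirely in replicated peaks, among them Hoxb13, Hoxb9, Hoxb1, Hoxc13, Hoxc10 and Hoxc4, which reached 100% in both replicates. In HoxA 5 of 11 promoters were marked and in HoxD 8 of 9. The part of HoxA from Hoxa7 to Hoxa11, genes used in the upper and lower arm of the limb, was covered by 5.65% in the replicated list and 7.39% ± 5.15 over the replicates. The part from Hoxa1 to Hoxa6 was covered by 60.5% ± 12.8, and the part from Hoxa13 to Evx1 by 49.2% ± 10.9. Hoxa9 and Hoxa10 had 0% of their windows in peaks in both replicates, and Hoxa11 had 15.8% in the replicated list, 10.7% in replicate 1 and 33.6% in replicate 2, where it passed the threshold. Hoxa13, a gene of the digit territory, had 34.8% ± 5.72. Hoxa3 had 0% at its 5' end, the start shared by most of its transcripts, and 67.1% at its best covered start. In HoxD the least covered part was Hoxd9 to Hoxd11, at 40.2% ± 15.5, between Hoxd12 to Hoxd13 (66.4% ± 13.6) and Hoxd1 to Hoxd8 (83.3% ± 7.11). The dip in HoxD exceeded the spread between replicates, but Hoxd10, the 1 unmarked HoxD promoter at 17.6%, had 13.5% in replicate 1 and 59.8% in replicate 2.

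**Figure D3:**
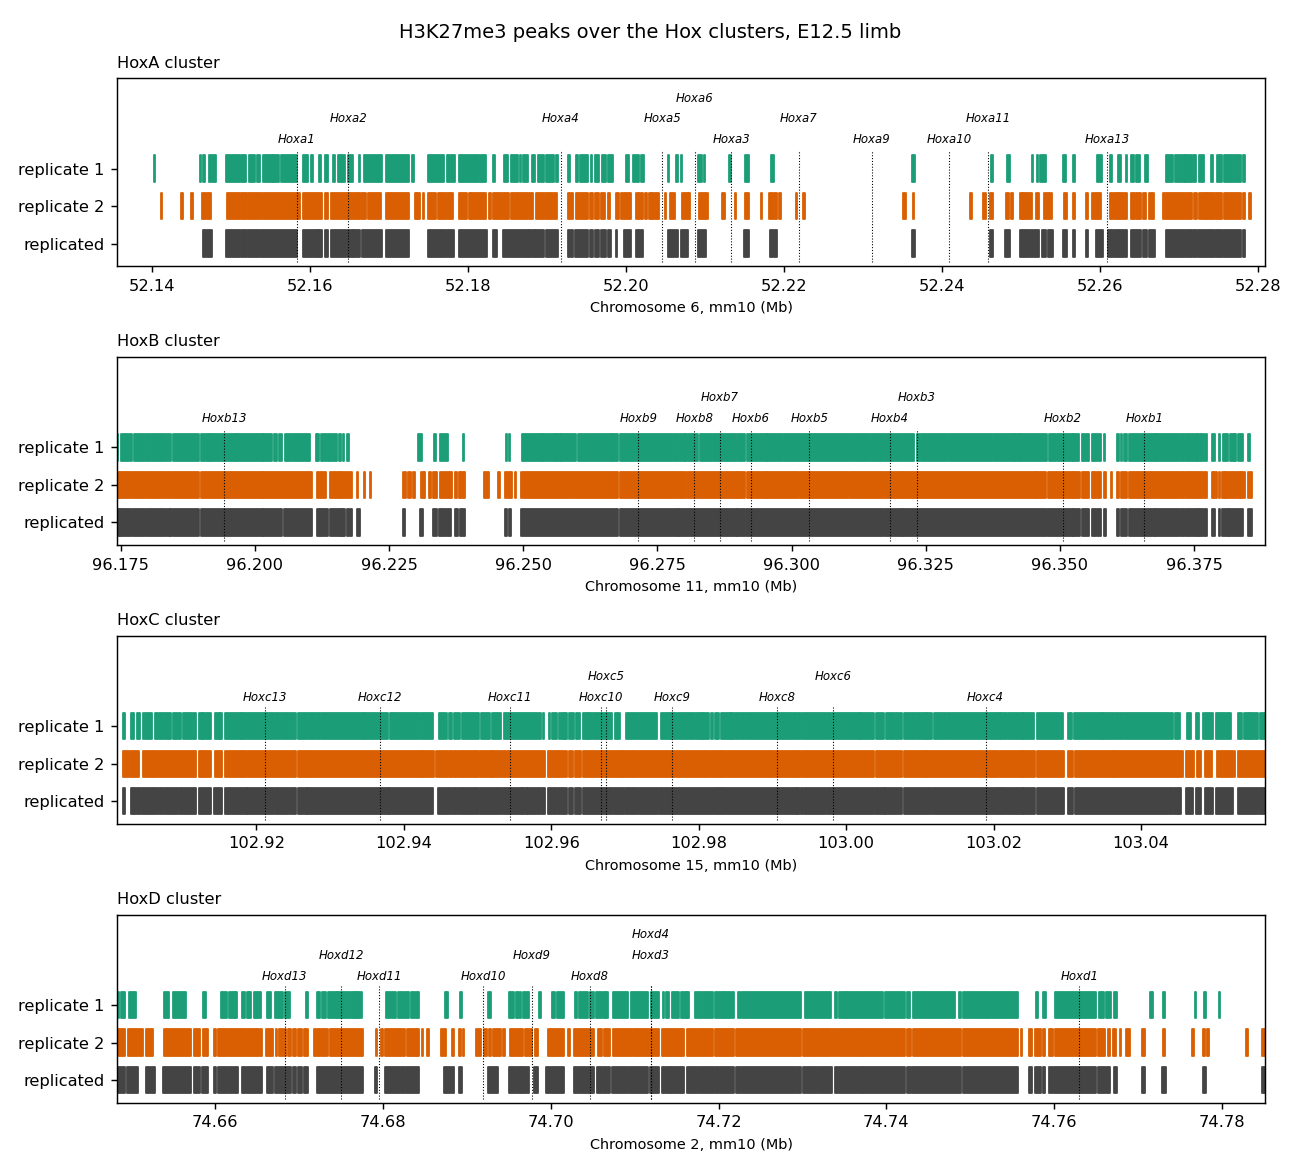
Peaks of replicate 1 (top track), replicate 2 (middle) and the replicated list (bottom) over the 4 Hox clusters with 20 kb on each side; the x axes are mm10 positions in Mb and dotted lines are annotated 5' ends. HoxC is nearly filled (94.4% in replicated peaks), while the part of HoxA from Hoxa7 to Hoxa11 is nearly empty (5.65%).

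The longest domain of joined peaks was HoxC, at 170.8 kb (chromosome 15, 102901913 to 103072742), of which 84.1% lay in peaks of replicate 1 and 91.1% in those of replicate 2. Next came domains at Irx3 (119 kb, chromosome 8, 91765562 to 91884740), the cadherin gene Cdh22 (110 kb), the muscle stem cell gene Pax7 (109 kb), the HoxB genes from Hoxb2 to Hoxb9 (109 kb) and Tbx3 (91.0 kb). The other genes with a 5' end in the 20 longest domains were Foxd2 and Foxe3, Dmbx1, Zic1 and Zic4, Pkdcc, Neurod2 with its neighbour Ppp1r1b, Pax2 and Tbx5. Tbx3, a T-box gene of the limb margins, had 49.4% of its window in peaks in replicate 1 and 87.4% in replicate 2. The peak with the highest signal value, 21.9, lay over Barhl1 (chromosome 2, 28905312 to 28920225), and others of the top 10 lay over the 5' ends of Adra2c, Celsr3, Neurog3, Kcnc1 and Insm2, which were named here after their values were seen. The median length of the 20 longest domains was 75.0 kb, 64.4 kb in replicate 1 and 83.3 kb in replicate 2. It changed with the joining gap, to 21.2 kb with no gap allowed and 208 kb with 5 kb, and only 3 and 9 of the 20 longest domains overlapped the 20 longest at these gaps.

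The X chromosome had the highest share of marked promoters of any chromosome. On X, 298 of 948 promoters were marked (31.4%), against 18.5% of 20780 autosomal promoters (odds ratio 2.02, Fisher's exact p = 1.14e-20), and single autosomes ranged from 13.6% (chromosome 16) to 26.5% (chromosome 15). The shares were 26.4% against 16.3% in replicate 1 and 31.9% against 18.5% in replicate 2. Among CpG-rich promoters the difference was wider, with 128 of 226 marked on X (56.6%) against 20.4% on autosomes (odds ratio 5.08). X held 13.5% of the replicated peaks and 6.28% of the genome, and its peaks had a median width of 459 bp. Peaks covered 3.53% ± 0.846 of its bases over the replicates (SD, n = 2). In the replicated list X was at 3.91%, with chromosome 11 above it at 4.29%, and in each replicate chromosome 19 was above it as well (3.28% against 2.93%, and 4.47% against 4.13%). On Y there was no replicated peak, and 0 of 183 promoters were marked. Replicate 1 had 1 peak on Y and replicate 2 had 0. The aligner was not given, so how well reads could be placed on Y was unknown. The pools held both sexes, so males and females could not be compared.

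**Figure D4:**
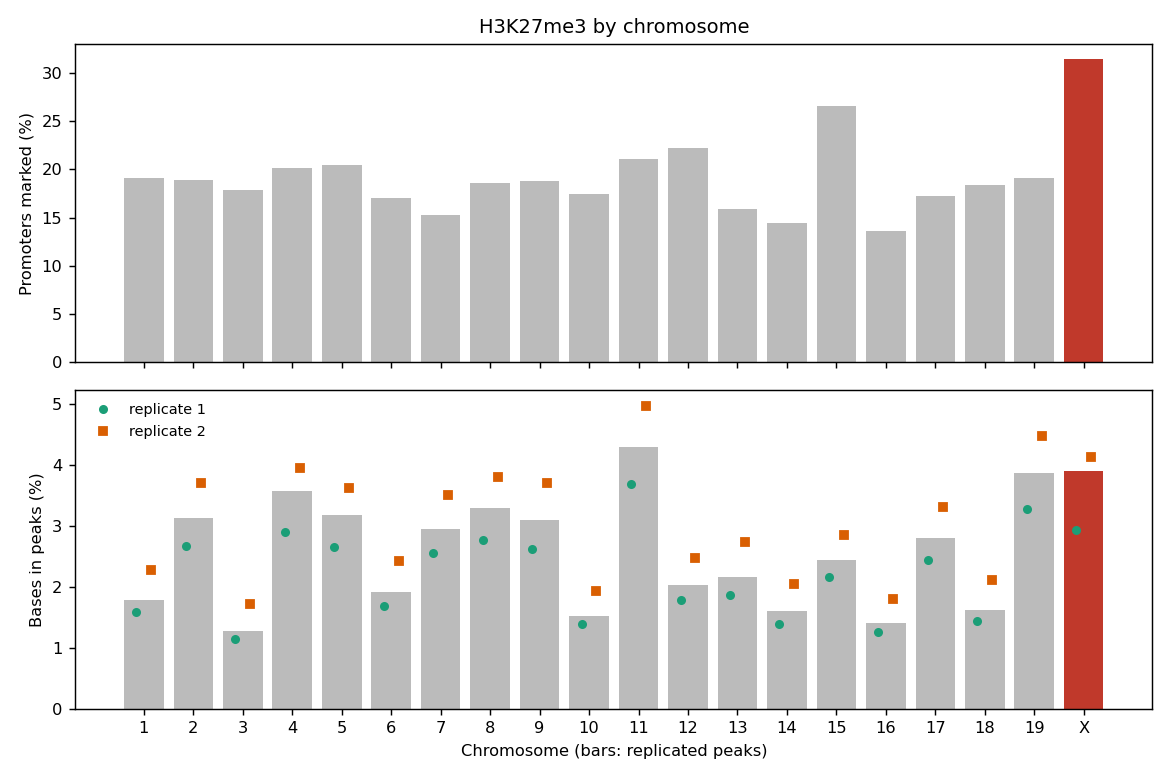
Share of protein-coding promoters marked (top, percent) and share of bases in peaks (bottom, percent) for chromosomes 1 to 19 and X (red). Bars are replicated peaks, circles replicate 1 and squares replicate 2; X is highest in promoters (31.4%) but not in bases, where chromosome 11 is higher (4.29% against 3.91%).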

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

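No test was added for this result. Replicate 1 had 4 peaks on unplaced scaffolds, sequences left out of the comparisons, where replicate 2 and the replicated list had 0 and the pooled list had 1.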

How the results depend on the processing

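The circular shift, the peaks found in both replicate lists, the start shared by most transcripts, the −log10 q of at least 5 and the comparison without olfactory receptors were chosen after the data were seen. Of 370 alternative values, 327 left the result the same. For the share of promoters marked and the shares of peaks in common, this meant a move smaller than the SD of the 2 replicates. The count therefore depends in part on how far the replicates differed. The calls for Hox genes, limb patterning, cartilage and bone, nervous system, gut, heart, ectoderm, neural crest, kidney, Wnt, housekeeping and olfactory genes and for X were kept in every alternative run. The share of promoters marked was 16.6% to 18.9% with 1 replicate left out, 21.5% in the pooled list, 14.6% in the intersection of the replicate lists, 23.3% at 1 bp, 14.9% at 50% and 22.1% with any start. The share of the genome was 3.90% pooled and 1.37% in the intersection. With neighbours as 1 locus, muscle (44.4%) and blood and endothelium (47.2%) lost their call. Pluripotency and germline lost it with replicate 2 left out (27.8% to 33.3% over the 2 replicates), in the pooled list (33.3%) and intersection (25%), with 500 bp and 2.5 kb windows (30.6% each), at 1 bp (33.3%) and 50% (27.8%), with any start (36.1%), CpG-rich promoters (25%), loci (34.3%), shared members left out (31.4%) and no olfactory receptors (33.3%). Polycomb components turned direction in the intersection (14.7%), with 2.5 kb (23.5%), 1 bp (29.4%) and any start (23.5%). Kinase inhibitors gained a call in the pooled list (57.1%) and with 2.5 kb, 1 bp and any start (71.4% each). CpG-rich promoters fell below others at a ratio of 0.75 (16.8%), and peak bases elsewhere in genes to 0.963 times chance with 2.5 kb windows, whose promoters take bases from that class. With 1 replicate left out and in the intersection, HoxA gave 30.5% to 45.2% and 25.6%, HoxB 73.6% to 80.9% and 72.0%, HoxC 86.5% to 93.0% and 85.2%, and HoxD 63.2% to 76.9% and 60.1%. The median of the longest domains was 102.1 kb pooled, 21.2 kb with no gap and 208 kb with 5 kb. The intersection and 1 bp settings change how much is covered by construction; otherwise the cause was not tested. No paired analysis of groups was possible because there is 1 group. Depth was unknown, so the longer list of replicate 2 cannot be told from a deeper library.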

Other observations

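The gene families, regions and comparisons of lists in the first 3 paragraphs, the lists of X-linked genes, the joining of HoxA with HoxD and HoxB with HoxC, the test of whole HoxA cover, the split of X at its middle, the counts of 5' ends in single replicates, the use of replicate 2 in the test of weak peaks, and the test of GC content were chosen only after the data were seen. Families were taken from the letters (at least 3) of the gene symbol before the first digit, and 254 families with at least 10 members, the olfactory receptors already described left out, were tested by Fisher's exact test with Benjamini-Hochberg adjustment: 30 were marked more often than other genes and 19 less often. All 14 Nkx homeobox genes were marked (exact adjusted p = 4.58e-09), as were 17 of 22 Fgf genes (exact adjusted p = 2.42e-07) and 12 of 19 Sox genes (exact adjusted p = 0.000573). Also marked were 14 of 17 synaptotagmin genes (Syt, exact adjusted p = 1.16e-06), 11 of 14 serotonin receptor genes (Htr, exact adjusted p = 6.28e-05) and 10 of 14 Kcnk potassium channel genes (exact adjusted p = 0.000573). The counts in replicates 1 and 2 were 14 and 13 for Syt and 11 in each for Htr. Solute carriers were marked at 113 of 371 promoters (30.5%, exact adjusted p = 2.09e-06).

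Several tissue-restricted families were among the least marked. None of 330 vomeronasal receptor genes (Vmn, exact adjusted p = 2.92e-28), 42 beta-defensin genes (Defb, exact adjusted p = 0.00315) or 34 X-linked Rhox homeobox genes (exact adjusted p = 0.0132) was marked in any of the 3 lists. Zfp zinc finger genes were marked at 22 of 394 promoters (5.58%, exact adjusted p = 2.19e-12), replication histone genes at 1 of 67 (exact adjusted p = 0.000573) and mitochondrial ribosomal protein genes at 0 of 49 (Mrpl, exact adjusted p = 0.00122). Many of these genes lie in clusters, so their p-values are too small. Compared directly, limb patterning genes were marked less often than nervous system transcription factors (45 of 59 against 74 of 76, exact adjusted p = 0.00101) and more often than skeletal muscle genes (17 of 37, exact adjusted p = 0.00917) and genes of blood and endothelium (17 of 39, exact adjusted p = 0.00407), while the threshold was not passed against surface ectoderm (exact adjusted p = 1), kidney and gonad or heart (0.317 each), or gut, liver, lung and pancreas (0.271). The difference from cartilage and bone (21 of 39) had an exact adjusted p of 0.0502 over 9 such comparisons. Some lists differed in promoter class, with 42 of 59 limb, 11 of 37 muscle and 6 of 39 blood and endothelium promoters CpG-rich. These comparisons were not repeated among CpG-rich promoters or over loci. Promoter class may therefore account for the differences from muscle and from blood and endothelium. In the nervous system list 53 of 76 promoters were CpG-rich, a share close to that of the limb list. This argues against CpG class, as defined here, for the difference between those lists.

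Regions between chosen landmark genes around limb regulators differed in cover, and some of them held protein-coding genes. From Hoxd1 to Hnrnpa3, the side of HoxD that holds its early limb enhancers (chromosome 2, 74765143 to 75659260), 15.8% ± 4.61 of bases lay in peaks, against 4.09% ± 1.51 from Atp5g3 to Evx2, the side that holds its digit enhancers (73911327 to 74652990; SD, n = 2), and the order was the same in each replicate. The region from Fto to Irx5, which contains Irx3 (chromosome 8, 91668440 to 92357624), had 62.1% ± 5.69 of its bases in peaks, and 4 of the 20 longest domains lay in or at the edge of it. The region between Shh and Mnx1, which contains the limb enhancer of Shh within Lmbr1, had 2.02% ± 0.379. Another domain, of 80.6 kb on chromosome 7, held no protein-coding 5' end but did hold the microRNA gene Mir9-3 and its host Mir9-3hg.

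The higher share of marked promoters on X than on autosomes has the inactive X of the female embryos as a candidate explanation, which stays open. X-linked housekeeping genes were marked at 18 of 47 promoters (38.3%) against 2 of 67 on autosomes (2.99%; Fisher's exact p = 1.1e-06). A uniform gain of called signal over X would give the same excess, so this test cannot tell the 2 apart. The marked X-linked housekeeping genes were 15 of the 18 beyond the middle of X (85.5 Mb) and 3 of the 29 before it. Over all genes, 51.0% of 445 promoters beyond the middle and 14.1% of 503 before it were marked, and the cause of this was not tested. Peaks near the calling threshold do not account for the whole difference, since the odds ratio was 1.91 at a −log10 q of at least 5. It was 1.95 with peaks found in both replicate lists. In the intersection of the replicate lists it fell to 1.48 (20.0% against 14.5%), so the size of the difference depended on cover that the replicates did not share. The test planned for a uniform gain of called signal over X did not decide. Genes known to escape X inactivation were marked at 3 of 10 promoters, against 18 of 47 (Fisher's exact p = 0.730). The 3 were Usp9x, Bgn and Mid1, named after their values were seen. A split of X, chosen after the values were seen, argued against a uniform gain. The parts before and beyond the middle differed by 36.9 points on X and by at most 15.7 on any autosome (53.4 and 13.5 among CpG-rich promoters). An inactive X would also act over the whole chromosome, so the split does not favour it over a uniform gain. Sex was not separated in these pools, so no direct comparison of females with males was made.

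Fewer promoters of HoxA and HoxD (13 of 20; HoxA 5 of 11, HoxD 8 of 9) than of HoxB and HoxC (19 of 19) were marked, with 10 of 20 in replicate 1 and 16 of 20 in replicate 2, but the clusters were grouped after these counts were seen and neighbouring genes are not independent, so the difference itself is not tested. GC content is argued against, since 5 of the 5 least covered windows lay within the GC range of the 16 fully covered ones (Spearman's rho 0.00509 over 39 genes, permutation p = 0.976). A 5' end away from the main promoter is argued against as the whole cause: at the start shared by most transcripts the counts were 13 and 19 again, and 5 of the 7 unmarked genes already had their 5' end there. With any start counted, which can only raise cover, 15 of 20 were marked (exact p = 0.0471), 12 in replicate 1 but 18 in replicate 2 (exact p = 0.487), while the share of the whole HoxA cluster in peaks, which uses no 5' end, lay 32.2 points below the next lowest cluster on average over the replicates. A continuous domain broken in calling was tested only on the windows of Hoxa7, Hoxa9, Hoxa10 and Hoxa11. They were covered by 8.88% ± 17.8 (SD over the 4 genes) after joining peaks over gaps of up to 5 kb. Broken calling is argued against for Hoxa7, Hoxa9 and Hoxa10, which lay in gaps longer than 5 kb. The unmarked Hoxa3, Hoxa5 and Hoxd10 windows and part of the Hoxa11 window lay in shorter gaps, which this joining closes. For these genes, and so for the difference in promoter counts, broken calling stays open. No biological explanation was tested.

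The low base overlap of the replicate lists (Jaccard index 0.369) was set against 2 technical explanations, and both stay open. In the strongest 20% of replicate 1 peaks by the authors' p, 90.2% were shared with replicate 2, and in the weakest 20% 38.9%, which met the bounds set beforehand, on replicate 1 alone, for weak peaks near the calling threshold as the explanation. The rule was changed after these values were seen to require the same bounds in replicate 2, which turned the verdict from met to undecided: in replicate 2 the strongest 20% was shared by only 75.2%, keeping peaks at a −log10 q of at least 2 raised the index only to 0.401, and strong peaks were wider (a median of 517 bp against 206 bp in replicate 1) under a 1 bp criterion. Continuous domains broken at different places were the other explanation: joining peaks over gaps of up to 1 kb raised the index to 0.432, a rise of 0.0637 that lay between the bounds set for and against this explanation. No biological explanation was tested.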
